A study of Mus musculus with 4 samples.

How the data were processed

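RNA was sequenced from gBT-I cells, CD8+ T cells that carry a transgenic T cell receptor for a peptide of herpes simplex virus glycoprotein B (residues 498 to 505). Per the labels' protocols, splenocytes were activated in culture with the peptide and LPS, were given an interleukin on days 2 and 3, and were injected into the vein of recipient mice on day 4. The recipients were C57BL/6 mice kept either specific pathogen free (SPF) or germ free (GF). Splenic gBT-I cells were enriched and sorted on day 7 after transfer, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit, which does not mark strand, and sequenced on a Genome Analyzer IIx. The 4 libraries are 2 of SPF and 2 of GF recipients.

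The deposited table holds whole-number read counts per gene, not normalized, with 1 column per library, matched to the samples by the column names in the labels. Per the submitters' processing notes, the build was mm10 and the tools were CASAVA, TopHat, Picard, featureCounts, Subread and edgeR. Their versions, settings and annotation are not given in the sources used here. The authors' table holds 24062 genes by symbol, of which 15353 have a count in any library, and no row without a gene name. Without strand, reads from where a gene and an antisense neighbour overlap cannot be told apart. Reads of near-identical genes may be split or lost in the counting.

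Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (11271 genes kept) and the quasi-likelihood F test of GF against SPF, without covariates. P-values are two-sided and were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values given per gene (counts scaled to library size) use the TMM-scaled library size, and are given as mean ± SD. Totals of marker lists use the plain library total.

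Gene lists, 36 in all, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists cover T cell programs, cell states, metabolism, RNA quality and markers of 11 kinds of other cells. The 29 lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The rule names up to 10 genes past the threshold in each direction, up to 4 members of each list by smallest p, the most abundant member of each list of other cells, and a panel of 18 CD8 T cell genes. Some genes that the rule names are not reported here. Genes outside it are marked in the text as chosen after their values were seen.

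Gene positions, exonic transcript lengths and GC content came from GENCODE mouse release M21 (GRCm38, the same assembly as mm10), which matched 99.3% of tested genes. Both steps were tested on simulated counts for this comparison over 11271 genes. With spread drawn without any structure by replicate number, the quasi-likelihood test recovered 15% of genes changed 2-fold and 69% of genes changed 4-fold, with 1 false call among 85. With the spread that same-numbered libraries share built in, it recovered 0% of either. A fit with the replicate number as a block then recovered 83% and 97%, with 6 false calls among 186. That simulation gave both groups the same difference by number, as the block fit assumes. In the data, genes in the decile of longest transcripts had a median log2 difference by number of 0.72 in SPF and 0.49 in GF. The simulation therefore cannot say how often the block fit makes false calls in these data. Camera with the preset correlation recovered a glycolysis list raised 1.5-fold in 100% of 50 runs and called 0.14% of the unraised lists. These runs drew each gene independently, with the spread of the block fit and no difference by replicate number. They cannot say how often the preset calls lists whose genes vary together. Estimated correlations in the data were 0.54 for mitotic and 0.89 for ribosomal protein genes.

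Alternatives covered scaling, filters on low counts, DESeq2 1.42.0, limma-voom, the edgeR exact test, robust fitting, the replicate number as a block, stricter and looser thresholds, removal of genes of other cells, and each library left out. Corrections for transcript length and GC content were chosen after seeing the data. The replicate numbers are shared by the groups, but no label says that they mark a shared animal, day or batch, so the libraries were treated as unpaired. Figures were drawn with matplotlib 3.10.9.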

Results

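The experiment asked how the transcriptome of activated CD8+ T cells differs after 7 days in mice with and without a microbiota. Total counts were 11544960 and 14026051 in SPF replicates 1 and 2, and 14219354 and 14431533 in GF replicates 1 and 2. A gene with 0 counts could hold up to 3 counts, or 0.26, 0.21, 0.21 and 0.21 CPM (counts scaled to library size) in these libraries, which covers counting error only. Counts differed between the replicates of a group by more than sampling noise, so each library was counted once. The chi-square per degree of freedom was 94.6 within SPF and 46.9 within GF. Between groups it was 19.5 for the libraries numbered 2 and 60.0 for those numbered 1. It was 31.4 for SPF replicate 2 against GF replicate 1, and 153.1 for SPF replicate 1 against GF replicate 2. Some libraries of different recipients were thus more alike than replicates. The labels do not say whether replicates came from separate mice, and p-values measure only the spread between these libraries.

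Itgae, which encodes the αE integrin (CD103) that binds E-cadherin, had the smallest p of all tested genes. It measured 30.2 ± 12.9 CPM in SPF and 187.4 ± 25.1 CPM in GF (SD, n = 2 each), a log2 fold change of 2.63 (SE 0.36). The killer-cell kinase gene Styk1 measured 5.38 ± 0.08 against 18.4 ± 0.5 CPM, and the chemerin receptor gene Cmklr1 4.06 ± 0.55 against 15.0 ± 3.4 CPM. H2-Q10, a class Ib MHC gene, was the one gene with lower values in GF among those called by another tool, at 114.7 ± 43.0 against 36.6 ± 4.3 CPM. Of the 11 genes called by another tool, all but Itgae and Mki67 were chosen after their values were seen.

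No gene passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, with 0 higher and 0 lower in GF among 11271 tested and a smallest adjusted p of 0.86. At an unadjusted p under 0.05 there were 363 genes, 245 higher and 118 lower, where 564 are expected by chance. These counts do not show that the groups are alike. The fit without covariates takes spread by replicate number as noise (common dispersion of 0.076, against 0.017 with the replicate block). With such spread simulated, the same test recovered 0% of genes changed 4-fold. DESeq2 called 8 genes higher and 1 lower, the edgeR exact test 8 and 1, and limma-voom 0 and 0, and 7 genes were shared by the first pair. In both, the genes were Itgae, Styk1, Gpr141, Cmklr1, Tppp3, Tbc1d2 and H2-Q10. DESeq2 added Mki67 and Spock2, and the exact test added Stmn2 and Wnt10b. For Itgae, the adjusted p was 9.84e-08 by DESeq2 and 3.65e-06 by the exact test, and it was 0.011 in the quasi-likelihood test adjusted over the list alone (tissue residency genes). The edgeR quasi-likelihood test called 15 genes higher and 2 lower without SPF replicate 1, and 783 and 544 without SPF replicate 2. The groups did not overlap for 33.2% of tested genes, where chance gives 33.3% if all orderings of the libraries are equally likely. The libraries differed by replicate number in both groups, so the orderings were not equally likely. The match therefore does not show a lack of difference. An exact two-sided permutation test of 2 libraries against 2 cannot give a p under 0.33.

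**Figure D1:**
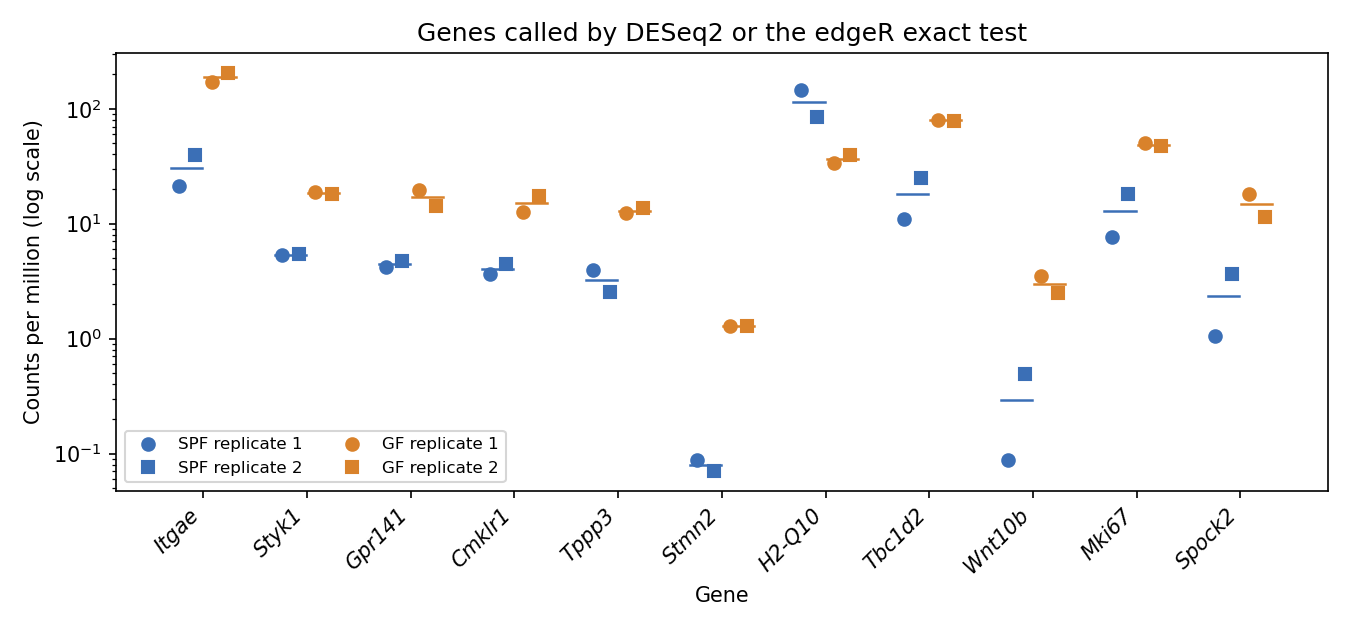
CPM on a log scale for the 11 genes called by DESeq2 or the edgeR exact test, with 1 point per library, replicate 1 as circles, replicate 2 as squares, and lines at the group means. Both GF libraries lie above both SPF libraries for 10 of the genes and below them for H2-Q10.

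In mm10, Itgae lies on chromosome 11 from 73090583 to 73147446 on the plus strand, with 31 annotated exons, and the gene Haspin (Gsg2 in the deposited table) lies inside it on the opposite strand. Gsg2, which encodes a mitotic histone kinase and was chosen after its values were seen, measured 19.5 ± 1.3 CPM in SPF and 36.4 ± 2.0 CPM in GF. Where exons of Gsg2 and Itgae overlap, reads cannot be told apart by strand, and whether exons overlap was not examined. H2-Q10 lies on chromosome 17 from 35470089 to 35474563. It has close relatives in the same cluster, so its reads may be shared. H2-Q4 and H2-Q5, picked for that reason, had log2 fold changes of 0.28 (SE 0.22) and 0.73 (SE 0.51). Stmn2 rests on 1 count in each SPF library and 19 and 18 counts in the GF libraries.

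Mitotic genes rose as a group in GF recipients by camera with the preset correlation (adjusted p = 1.49e-11). The call was lost by camera with an estimated correlation (adjusted p = 0.82). In that setting 0.82 was the smallest adjusted p of all 29 lists, so a lost call there does not tell the lists apart. Of 30 tested members, 27 had higher mean values in GF, 19 had both GF libraries above both SPF libraries, and the median log2 fold change was 1.04. Mki67, the gene of the proliferation antigen Ki-67, measured 12.9 ± 7.5 CPM in SPF and 48.8 ± 1.6 CPM in GF. Top2a, the topoisomerase that untangles chromosomes, measured 25.8 ± 11.9 against 54.4 ± 9.3 CPM, and the spindle motor gene Kif11 4.24 ± 0.19 against 9.70 ± 3.39 CPM (both chosen after their values were seen). Espl1 (separase), Cenpf (a kinetochore protein) and Hmmr (a spindle protein) were near the detection limit in SPF, at 0.12, 0.27 and 0.32 CPM, against 1.66, 2.01 and 1.22 CPM in GF.

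No mitotic gene passed the edgeR test over all genes, and 0 passed it adjusted over the list alone. Within replicate number 1, GF exceeded SPF by a median log2 value of 1.54, and within number 2 by 0.58. DNA replication genes did not pass (adjusted p = 0.69 with the preset correlation): 20 of 40 were higher and 20 lower in GF. Among them E2f2, a transcription factor of the S phase program, measured 101.8 ± 4.3 CPM in SPF and 204.7 ± 1.5 CPM in GF, while the primase subunit gene Prim1 measured 24.95 ± 1.52 against 15.8 ± 0.1 CPM. Chaf1a, a histone chaperone subunit, had a log2 fold change of 1.30 (SE 0.44).

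**Figure D2:**
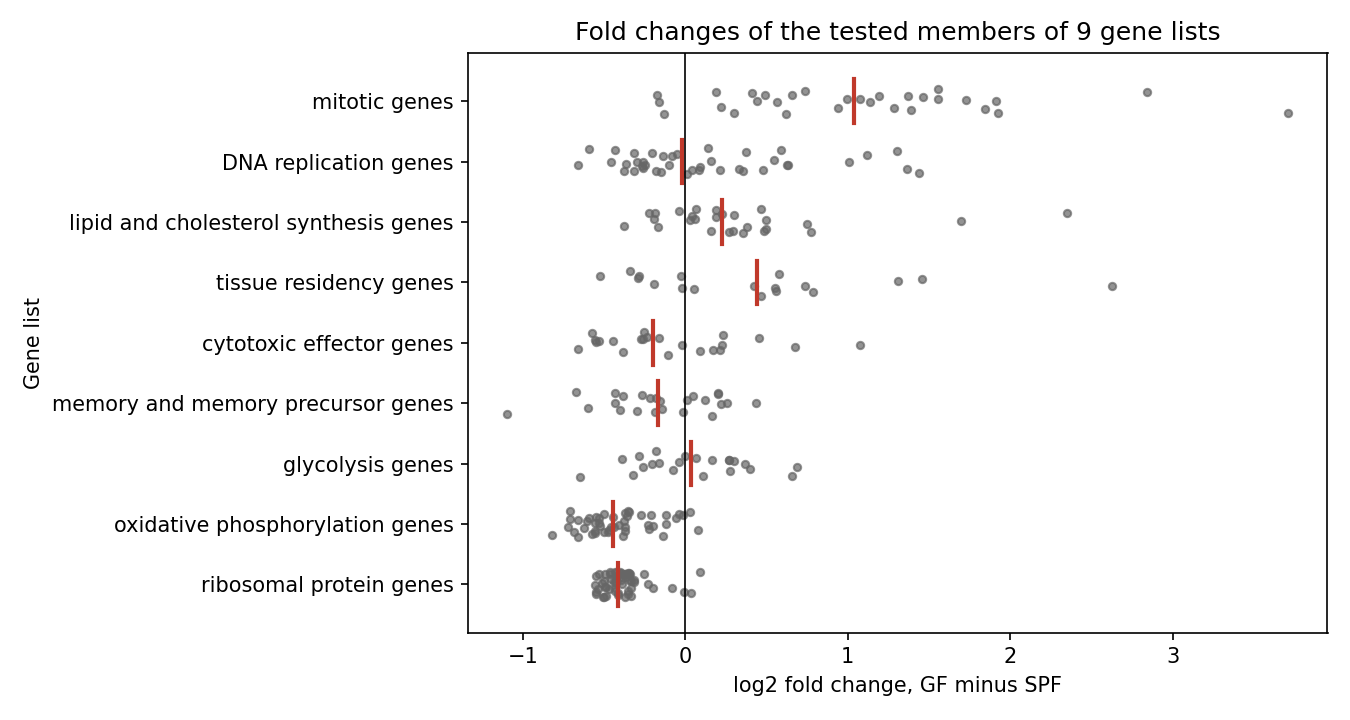
Log2 fold change of GF against SPF for each tested member of 9 gene lists, with 1 point per gene and a red line at the median of the list. Mitotic genes have a median of 1.04 and oxidative phosphorylation and ribosomal protein genes medians of -0.44 and -0.41.

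Genes of lipid and cholesterol synthesis also rose as a group by camera with the preset correlation (adjusted p = 0.0051). This call was lost as well by camera with an estimated correlation (adjusted p = 0.82, unadjusted p = 0.097). The estimate for this list was 0.025, near the preset of 0.01. Of 27 tested members, 21 had higher mean values in GF and 13 had both GF libraries above both SPF libraries, with a median log2 fold change of 0.23. The stearoyl-CoA desaturase genes Scd1 and Scd2 measured 3.17 ± 1.19 CPM in SPF against 10.3 ± 3.7 CPM in GF and 95.2 ± 32.7 against 162.8 ± 20.3 CPM, and Srebf1, a transcription factor of lipid synthesis, 117.1 ± 9.2 against 165.1 ± 10.03 CPM. The call of the list was also lost without SPF replicate 2 and without GF replicate 1. It was lost as well with the replicate number as a block and a correction for transcript length (camera adjusted p = 0.074 with the preset correlation).

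Ribosomal protein genes and genes of oxidative phosphorylation had lower values in GF, and both lists passed camera with the preset correlation (adjusted p = 1.82e-07 and 4.07e-05). Both calls were lost without that preset (adjusted p = 0.82 with an estimated correlation for both). Of 57 ribosomal protein genes 55 had lower mean values in GF, with a median log2 fold change of -0.41, and of 47 oxidative phosphorylation genes 45 did, with a median of -0.44. Rplp1 of the large and Rps24 of the small ribosomal subunit had values of 1091.4 ± 423.2 CPM in SPF against 743.8 ± 93.6 CPM in GF, and 1182.2 ± 401.5 against 827.1 ± 97.6 CPM. Cycs (cytochrome c) had 137.6 ± 68.3 against 83.9 ± 12.3 CPM, and Ndufa5, of respiratory complex I, 31.8 ± 17.5 against 18.0 ± 3.6 CPM. Only 1 ribosomal and 2 oxidative phosphorylation genes had both GF libraries below both SPF libraries.

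GF replicate 1 lay above SPF replicate 2, by a median of 0.14 for the ribosomal and 0.29 for the oxidative phosphorylation list. Both lists consist of short transcripts (medians of 1128 and 1410 nt against 3318 nt over tested genes), and differences between libraries followed transcript length. Across 11194 genes, which are not independent replicates, Spearman's rho with length was 0.56 for SPF replicate 2 minus 1, 0.51 for GF replicate 2 minus 1 and 0.39 for GF minus SPF. Without SPF replicate 1, neither list passed (adjusted p = 0.68 and 0.75), and oxidative phosphorylation was also lost without GF replicate 2 (adjusted p = 0.081). With the length trend removed, a correction chosen after seeing the data, neither passed (adjusted p = 0.10 and 0.11). With length and GC trends removed both did with the preset correlation (adjusted p = 0.0075 and 0.022).

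**Figure D3:**
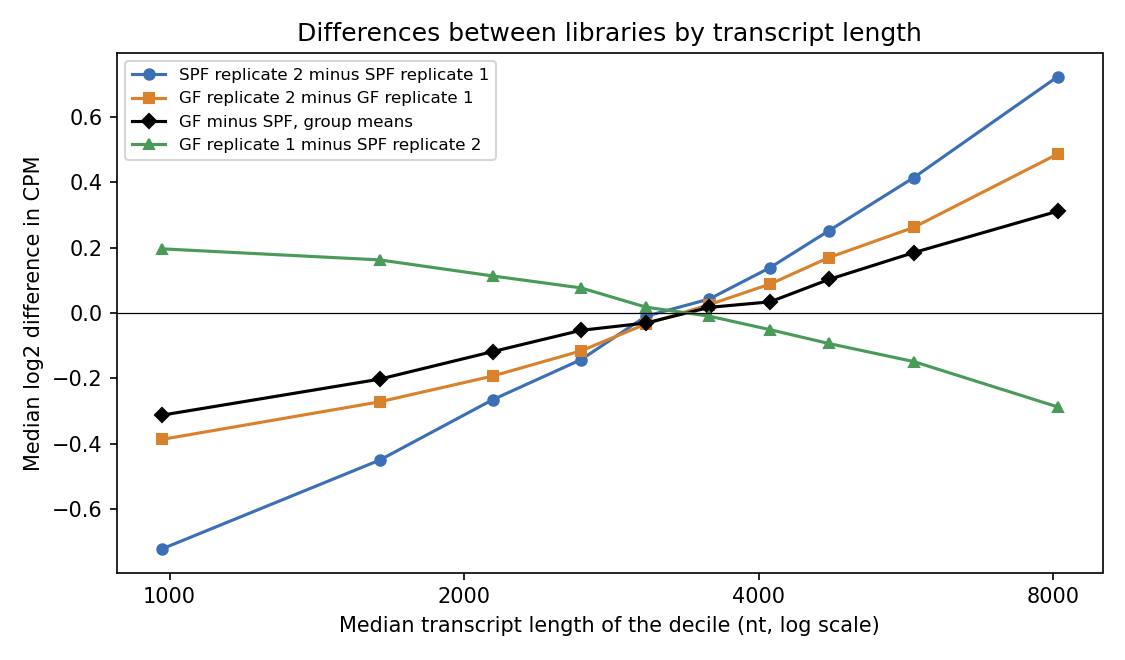
Median log2 difference in CPM between libraries or groups for deciles of the tested genes, ordered by transcript length in nucleotides on a log axis. For the longest decile the median is 0.72 for SPF replicate 2 minus SPF replicate 1, 0.49 for GF replicate 2 minus GF replicate 1, and -0.29 for GF replicate 1 minus SPF replicate 2.

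No T cell program list passed in the setting fixed beforehand with all 4 libraries, though tissue residency, early response, cytokine receptor and terminal effector genes did in some other settings. Tissue residency genes had a median log2 fold change of 0.44 and 11 of 18 higher in GF (adjusted p = 0.054). Beside Itgae they included the orphan nuclear receptor gene Nr4a1, at 9.46 ± 1.40 CPM in SPF against 26.0 ± 14.3 CPM in GF, and the checkpoint receptor gene Ctla4, at 64.7 ± 8.4 against 94.9 ± 4.2 CPM. Among 19 inhibitory receptor and exhaustion genes 13 were higher (adjusted p = 0.093), with Tigit at 29.8 ± 2.5 against 50.5 ± 4.2 CPM, Lag3 at 43.8 ± 0.7 against 74.6 ± 11.3 CPM and Pdcd1 (PD-1) at 4.28 ± 1.24 against 8.29 ± 0.12 CPM. T cell receptor early response genes had 18 of 24 higher (adjusted p = 0.067), and cytokine receptors and signalling 21 of 32 (adjusted p = 0.05004). Only 4 early response genes had both GF libraries above both SPF libraries. Median log2 differences of GF replicate 1 minus SPF replicate 2 were -0.10 for early response, -0.04 for tissue residency, -0.05 for cytokine and -0.001 for inhibitory receptor genes. For replicate 2 minus 1, early response genes had medians of 0.30 in SPF and 0.56 in GF, and tissue residency genes 0.39 and 0.70. The cytokine list held Tgfbr3, a TGF-β co-receptor, at 10.2 ± 0.7 against 21.7 ± 4.5 CPM and Il6ra at 4.72 ± 2.72 against 14.1 ± 2.3 CPM. Tissue residency and cytokine receptor genes had long transcripts (medians of 4683 and 4058 nt), and their median folds were 0.27 and 0.05 with the length trend removed. With that removal, adjusted p by camera with the preset correlation was 0.13 for tissue residency and for early response genes. It was 0.29 for inhibitory receptor and 0.28 for cytokine genes. Without GF replicate 1 all 4 of these lists passed upward with the preset correlation, the only one examined where a library was left out, with adjusted p = 3.96e-05 for tissue residency, 5.50e-05 for early response, 0.017 for inhibitory receptor and 0.022 for cytokine genes. Without SPF replicate 2 the tissue residency and early response lists passed (adjusted p = 0.041 each), and without GF replicate 2 they had adjusted p = 0.91 and 0.92.

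Cytotoxic effector genes had 14 of 22 lower in GF (adjusted p = 0.15). Their transcripts were short (median 1500 nt), and their median log2 fold change was -0.20, but 0.11 with the length trend removed. The pore-forming Prf1 had 90.6 ± 18.6 CPM in SPF against 62.7 ± 7.9 CPM in GF, and Fasl 54.6 ± 6.6 against 37.1 ± 3.9 CPM. Gzmb had a log2 fold change of 0.09 (SE 0.24). Among 24 terminal effector genes (adjusted p = 0.62) Lgals3 had 146.9 ± 31.3 against 303.6 ± 57.1 CPM, Cx3cr1 5.43 ± 1.51 against 12.3 ± 4.8 CPM, and the sphingosine phosphate receptor gene S1pr5 1.03 ± 0.15 against 0.24 ± 0.04 CPM. Memory and memory precursor genes had 15 of 24 lower (adjusted p = 0.25), with Eomes at 16.6 ± 0.4 against 10.9 ± 2.3 CPM, Bcl6 at 7.01 ± 0.22 against 3.28 ± 1.64 CPM and Ccr7 at 93.9 ± 31.8 against 58.8 ± 16.7 CPM. Foxo1 had 199.3 ± 2.2 against 269.2 ± 32.0 CPM. Naive and quiescence genes (adjusted p = 0.55), trafficking receptors (0.79) and costimulatory genes (0.44) did not pass.

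In the fixed panel, log2 fold changes within 0.25 of 0 were found for the co-receptor gene Cd8a (0.17, SE 0.23), the adhesion receptor gene Cd44 (-0.25, SE 0.21), the IL-7 receptor gene Il7r (-0.18, SE 0.24) and the activation marker Cd69 (-0.19, SE 0.22). The same held for the transcription factor genes Tcf7 (0.17, SE 0.21) and Tbx21 (0.06, SE 0.24) and the survival gene Bcl2 (0.05, SE 0.24). Id2 had -0.43 (SE 0.29), Id3 -0.27 (SE 0.44), Ifng 0.46 (SE 0.61), Cpt1a 0.39 (SE 0.35) and Klrg1, at 1.73 ± 0.64 CPM in SPF, -0.85 (SE 0.68). None of these passed the edgeR test.

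Other metabolic lists did not pass. Short-chain fatty acid sensing and use genes, which respond to products of gut bacteria, had 6 of 12 higher and 6 lower with a median of 0.08 (adjusted p = 0.75), including Acss1 (0.46, SE 0.21) and the histone deacetylase genes Hdac2 (-0.40, SE 0.23) and Hdac5 (0.36, SE 0.22). Glycolysis genes had a median of 0.03 (adjusted p = 0.63), with Hk2 at 10.4 ± 0.2 CPM in SPF and 16.5 ± 3.3 CPM in GF. Fatty acid oxidation genes had a median of -0.00 (adjusted p = 0.97), with the enoyl-CoA isomerase gene Eci1 at 36.1 ± 6.2 against 25.1 ± 0.1 CPM. The citrate cycle and glutamine list (adjusted p = 0.60) and mTORC1 and MYC targets (adjusted p = 0.26) held Suclg1 (-0.71, SE 0.34) and the mTORC1 inhibitor gene Ddit4, at 48.1 ± 10.3 against 108.4 ± 42.3 CPM.

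Type I interferon response genes had 26 of 34 lower in GF, a median of -0.15, and did not pass (adjusted p = 0.062). Isg15 had 15.1 ± 8.3 CPM in SPF against 7.56 ± 0.64 CPM in GF and Ifit1 25.4 ± 10.7 against 15.1 ± 1.4 CPM, while the antiviral GTPase gene Mx1 had 41.1 ± 0.8 against 60.1 ± 1.4 CPM. The interferon list passed downward without SPF replicate 2 (adjusted p = 0.024) and without GF replicate 2 (adjusted p = 0.010). Heat shock and dissociation stress genes had 12 of 24 lower (adjusted p = 0.34). In 10 of the 24 both GF libraries lay below both SPF libraries, and in 0 above. The chaperone genes Dnaja1 and Hsph1 had 452.5 ± 98.0 against 242.3 ± 54.6 CPM and 252.5 ± 44.5 against 117.1 ± 71.0 CPM. Apoptosis and survival genes (adjusted p = 0.20) and histone genes without a polyA tail (0.18) did not pass. The heat shock and histone lists passed downward without SPF replicate 1 (adjusted p = 0.0010 and 0.00085) and without GF replicate 2 (adjusted p = 0.0031 and 0.00064).

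B cell markers followed the replicate number and not the recipient. Their total was 132.5 CPM in SPF replicate 1 and 165.4 CPM in GF replicate 1, against 31.4 and 32.2 CPM in the libraries numbered 2. Of the 19 tested markers 17 had higher mean values in GF and 2 lower, and 5 genes of the list also stand in other lists. Cd74, the invariant chain of MHC class II, had 22.0 and 33.2 CPM in the libraries numbered 1 and 1.34 and 1.79 CPM in the others. The list did not pass between groups (adjusted p = 0.78), and B cell markers were called in each of the 4 comparisons with a library left out, in both directions. NK cell markers had 8 of 11 lower in GF (adjusted p = 0.067), with Cd7 at 281.7 ± 66.7 against 162.2 ± 22.3 CPM and Fcer1g at 8.92 ± 4.32 against 3.64 ± 0.61 CPM. Dendritic cell (adjusted p = 0.78), macrophage and monocyte (0.60) and CD4 and regulatory T cell markers (0.55) did not pass. NK cell markers passed downward without GF replicate 1, and dendritic cell markers upward without SPF replicate 1 and without GF replicate 2. Each of these fits leaves a lone library in a group. B cell markers passed upward in the same settings as the dendritic cell list, and both lists hold H2-Aa, H2-Ab1, H2-Eb1 and Cd74. The dendritic cell calls therefore cannot be told apart from the B cell marker difference between replicate numbers.

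Of the lists too short to test as a set, the gamma-delta T cell list had 4 tested genes, and Cd163l1 (20.3 ± 2.8 against 35.9 ± 1.3 CPM) and Maf (10.8 ± 0.2 against 20.1 ± 2.9 CPM) had an edgeR adjusted p of 0.033 adjusted over the list alone and 0.86 over all genes. Medians were 0.36 for 4 plasma cell, 0.12 for 3 erythroid and 0.25 for 4 megakaryocyte and platelet markers, and the 1 tested stromal marker, Pecam1, had 0.18 (SE 0.20). No neutrophil marker was abundant enough to test, and mitochondrially encoded genes were not analysed here.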

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

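The length and GC corrections were chosen after seeing the data. The count of 0 genes higher and 0 lower in GF also came from other scalings (DESeq2 size factors, upper quartile, library totals), every filter on low counts, robust fitting, limma-voom, thresholds of 0.01 and 0.1, removal of genes of other cells, and the length and length with GC corrections. DESeq2 called 8 higher and 1 lower, and the edgeR exact test 8 and 1. With each library left out in turn, calls ranged from 0 to 783 higher and 0 to 544 lower, the most without SPF replicate 2. The lone library of a group is then assumed to vary like the others, and the cause was not tested. The labels tie same-numbered libraries across groups by that number alone. Across tested genes, the log2 CPM difference between the numbers in SPF correlated at 0.71 with that in GF, from 2 pairs of libraries. Genes are not independent replicates, and both differences followed transcript length (Spearman's rho of 0.56 in SPF and 0.51 in GF). With the replicate block 786 genes were higher and 420 lower, among them all 11 genes that DESeq2 or the exact test called. With the replicate block and the length trend removed, 94 were higher and 23 lower, of which 103 were among the 1206 called with the block alone. The share of false calls among the 1206 is not known, since the simulation of the block fit gave both groups the same difference by number.

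Against 4 lists with the preset correlation, 0 passed with an estimated correlation and 0 with fry, 7 with a filter of 5 CPM, 6 to 9 with a library left out, 6 with the replicate block, 2 with the length trend removed and 2 with the replicate block and the length trend removed. Mitotic genes passed upward in 13 of 15 alternatives, lipid synthesis in 10, ribosomal proteins downward in 10 and oxidative phosphorylation in 9. All of these passes kept the preset correlation of 0.01, so they are not independent support. The estimated correlations were 0.54 for mitotic, 0.025 for lipid synthesis, 0.89 for ribosomal protein and 0.86 for oxidative phosphorylation genes. With them, unadjusted p by camera was 0.18, 0.097, 0.42 and 0.47 in that order. After adjustment all of these became 0.82, the smallest value of any list, so that setting does not rank the lists. Lists gained, all with the preset correlation, were early response genes with the replicate block, with the replicate block and length trend removed and with the 5 CPM filter, tissue residency genes with that filter, library totals, a prior count of 5 and the length with GC correction, cytokine receptors with the filter, library totals and that prior count, interferon genes with the block, and terminal effector genes with the length with GC correction. With the block, early response and interferon genes did not pass with an estimated correlation (adjusted p = 0.95 for both) or fry (adjusted p = 0.52 and 0.64). Of 1867 alternative values for the 138 named genes, 43 changed sign and 102 passed the threshold, none of them with the sign changed. Depth limits genes such as Espl1 and Cenpf, which have few counts in SPF.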

Other observations

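All tests of explanations here were chosen after the results were seen, except that of TGF-β target genes.

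Some chaperone and cochaperone genes, picked because of their lower values in GF, were Fkbp4 (206.2 CPM in SPF and 115.7 CPM in GF), Stip1 (185.5 and 104.0 CPM), Chordc1 (164.1 and 93.4 CPM) and Ptges3 (195.9 and 100.4 CPM). None passed the edgeR test, and picked genes cannot speak for chaperones as a group. The heat shock and dissociation stress list, fixed beforehand, had 12 genes higher and 12 lower with a median log2 fold change of -0.05 (adjusted p = 0.34). Of its 24 tested genes, 10 had both GF libraries below both SPF libraries and 0 had both above. Over all 11271 tested genes, 1843 lay below and 1894 above in this way. The stress-induced Hspa1a and Hspa1b followed the replicate number, with Hspa1b at 1.66 and 3.69 CPM in SPF and GF replicate 1 and 17.9 and 19.3 CPM in replicate 2.

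Other genes with small p-values, also chosen after values were seen and not past the edgeR test, included the cholesterol exporter Abca1 (10.7 CPM in SPF, 26.2 CPM in GF), Esm1 (5.18 and 16.1 CPM), the transcriptional repressor Zbtb32 (3.14 and 11.3 CPM) and Tspan2 (13.6 and 33.1 CPM). The immediate early gene Fos, chosen likewise, varied between all libraries, and had 4.28 and 46.0 CPM in SPF and GF replicate 1 and 135.4 and 185.1 CPM in replicate 2.

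The libraries numbered 1 and 2 differed within both groups, and the first principal component, with 74.0% of the variance, ran from SPF replicate 1 to GF replicate 2. A genomic DNA source is argued against: the rise of olfactory receptor genes per kilobase was at most 0.058% of that of the longest decile of tested genes. B cell RNA as the whole source is argued against: in number 1 it would dilute genes that T cells but not B cells express at least as much as any others, yet the medians of 31 such genes for number 2 minus 1 were -0.24 in SPF and -0.07 in GF, and their upper quartiles lay below the medians of the longest decile (0.72 and 0.49) by at least 0.23, while an earlier test, the correlation of these genes between SPF and GF (0.57, 95% interval 0.27 to 0.77), had not excluded it. A bias by transcript length may contribute, as the smaller of the within-group rank correlations with length was 0.51, though length accounted for 24.6% of the variance in SPF and 19.5% in GF. What else separates the numbers stays open.

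The higher mitotic genes in GF are not accounted for by the length trend alone: on group means of log2 CPM, which differ from the edgeR fold changes, their median was 1.10 before and 0.93 after its removal (quartiles 0.44 and 1.32), and the list stayed past the threshold with the preset correlation (adjusted p = 3.47e-09) but not with an estimated correlation (adjusted p = 0.88), as before the removal. Dividing B cells as the source are argued against, since the median B cell marker differed by at most 0.26 within a replicate number, below the lower quartiles of the mitotic genes in number 1 (0.55) and, with a median of 0, in number 2 (0.21). B cell marker RNA was present despite the sort for gBT-I cells. The microbial status of the recipients, which the design names, stays open and untested as a source, and DNA replication genes went both ways (20 higher and 20 lower in GF, median -0.02).

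For ribosomal protein and oxidative phosphorylation genes, removing the length trend moved the medians of the same log2 CPM differences from -0.38 to -0.063 and from -0.39 to -0.083 and ended both calls, because the folds shrank. With GC content removed as well, medians were -0.14 and -0.12 and both lists passed again with the preset correlation. Length bias and a difference between recipients cannot be told apart for these lists, because the 2 corrections give opposite calls with that preset. These calls take a correlation of 0.01, where the estimates were 0.89 and 0.86. Before correction, only 1 of 57 and 2 of 47 genes had both GF libraries below both SPF libraries.

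A hypothesis written before their values were seen was that higher Itgae, a TGF-β target, goes with a wider rise of TGF-β feedback and target genes. Of 10 tested genes 7 were higher in GF, with a median of 0.16 (camera p = 0.12 with the preset correlation). With the length trend removed, the median log2 CPM difference was 0.035. The hypothesis stays open. Pmepa1 had 0.71 CPM in SPF and 1.98 CPM in GF and Smurf1 27.4 and 48.0 CPM, while Smad7 had 120.0 and 120.6 CPM.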
